A study of Drosophila melanogaster with 5 samples.

How the data were processed

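Whole-animal total RNA of IPC-deficient and control females was compared on 5 two-colour spotted arrays, 2 with IPC-deficient RNA in Cy5 and 3 with it in Cy3. The arrays came from 2 biological repeats, and which array held which repeat is not given in the sources used here. Each array had been scanned 3 times at different gains, and both spot copies and all hybridisations had entered the authors' normalization, per the labels and the design text. Background correction, the method of normalization and the filter behind empty cells are not given in the sources used here.

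The values deposited by the authors were signed fold changes: 0 of 29507 features with a value had an absolute value under 1, so a negative number is a fold in the opposite direction. Of 27376 features with 2 or more columns filled, 0 differed between columns by more than 1e-06, and of 14535 probes with both copies filled, 0 differed between copies by more than that. The table therefore held 1 combined value per probe and not 5 measurements. Because of this, the limma model foreseen for separate array values, its leave-one-out fits and its dye term were not run, and the rule of size fixed for this case was used instead. The numerator of the fold is not stated. Column medians on the log2 scale were 0.00, 0.01, -0.00, 0.00 and 0.00 for arrays 1 to 5, and the values are centred close to 0.

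Each signed fold change was turned into a log2 value by taking log2 of its size and keeping its sign. The 32448 features formed 16224 probes, each a pair of spot copies 2 blocks apart, of which 14972 had a value, 10299 on all 5 arrays and 6266 in all 10 spots. The number of filled spots, at most 10, served as the measure of how well a probe was measured, since intensities were not analysed here. The number of arrays limits the precision. In the annotation of 2007, 12536 probes had 1 gene symbol, 3 several and 3685 none. Symbols were updated for 12068 probes through the Entrez identifier and for 113 through the transcript accession, with a RefSeq gene table of Release 6, and 355 kept the name in the annotation. No genome build is named for the arrays, so no coordinates are printed, and the gene table was used only for names and for which genes neighbour each other. A gene's value was the median over its probes, counting probes with values equal to 5 decimals once. Of 10124 genes, 1167 had 2 or more probes of different value. As a measure of error, the SD between different probes of a gene was pooled over genes, giving 0.18 for probes on all 5 arrays and 0.56 for all probes (1167 genes with 2649 probes). It covers differences between probes and not between flies.

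Before the data were examined, the threshold of 1.5-fold, the gene lists, the tissue markers and the rule for named genes were fixed. The rule named tobi and the measured insulin-like peptides, the 12 highest and 12 lowest genes among those with a value on every array, and up to 4 members furthest from 0 in each list. A value on every array was taken to mean that each measured probe of the gene had one. This strict reading was chosen after the values were seen, because a reading that asked for 1 such probe would have added 11 genes (Pym, Hsp27, scaf, CG9863, PIG-C, CG13049, Lk, 5-HT2B, Gbs-70E, KrT95D and AttB), and all 11 had probes over 1 log2 unit apart. Genes named outside the rule are marked where they appear.

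List medians were set against the medians of 10000 random lists of the same size drawn from all measured genes, with seed 20. Lists with fewer than 3 measured genes were given as single values. The table holds no expression level, so random lists could not be matched on it, and a match on usable spots was added after the data were examined, as was a reassignment of the Mst57D genes from the testis to the accessory gland markers. Intervals of medians came from 10000 bootstrap draws over genes at the 95% level (1000 draws for the median of all genes), and intervals of shares from Wilson's method, and neither covers the spread between flies. In simulated shifts of lists of 20 genes drawn at random from the 10124 gene values, 4 of 100 lists without a shift were called. With a shift of 0.2 or 0.4, 100 of 100 were called each time. Lists of related genes were not simulated. In simulated placements of calls over 8112 array positions, the count of neighbouring calls was called in 5 of 200 scattered and 190 of 200 clustered placements. The alternatives tried were a 2-fold threshold, centring of each column, genes on all 5 arrays, other ways of joining probes, the sign turned, and random lists from genes on all 5 arrays. Probes without a gene symbol entered no comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.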

Results

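The series measured transcripts in whole adult Drosophila melanogaster females, 14 days old, that had fed on yeast paste for 48 h. Females lacking the insulin-producing cells, a small group of neurosecretory brain cells that release insulin-like peptides, were set against control females. The cells had been removed by driving the cell death genes reaper and hid with the InsP3-Gal4 line, and the control females carried the same driver with a LacZ transgene. Both RNAs were hybridised together on 5 two-colour arrays made from 2 biological repeats. IPC-deficient RNA (IPC, insulin-producing cell) was labelled with Cy5 on arrays 1 and 2 and with Cy3 on arrays 3, 4 and 5. Of 32448 spotted features, 25151 had a value on array 1, 20786 on array 2, 28090 on array 3, 21804 on array 4 and 20711 on array 5. After spot copies and probes were joined, 10124 genes had a value, and 6564 of them had every measured probe on all 5 arrays. The authors deposited a single signed fold change per probe, identical on every array, so no spread between arrays or flies could be computed and no test was possible. The error given instead is the SD between different probes of the same gene, 0.18 on the log2 scale (647 genes with 1437 probes on all 5 arrays).

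The first question was how the products of the ablated cells and the insulin pathway stood in the deficient flies. Ilp2, an insulin-like peptide made by these cells, had a log2 value of 0.01 from 4 of 10 possible spots, so its 1.01-fold value gave no check of the ablation. Ilp7 stood at -0.02 and Ilp8 at 0.07, both within the SD between probes, and Ilp3 and Ilp5 were not analysed here. In contrast, tobi, an alpha-glucosidase gene whose name stands for target of brain insulin, stood at -4.10, a 17.1-fold difference from 9 spots. None of the 12 measured genes of insulin and TOR signalling reached 1.5-fold, and their median was -0.03, with the insulin receptor InR at -0.15, Akt at -0.14, Pdk1 at -0.18 and gig at -0.14. The 5 measured genes known to be induced by the transcription factor FOXO had a median of -0.03, with Lip4 at 0.12 and Sesn at -0.03. Direction is not stated in the deposited table, and a negative value is here read as lower in IPC-deficient flies. That reading is likely, since the design names the deficient flies first and tobi is negative, so the sign of tobi is part of this basis and not a separate result. With the sign turned, every direction in the text would be the opposite.

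Among genes measured on all 5 arrays, the negative side after tobi was led by Nepl15, which encodes a neprilysin-like protein, at -3.11 (8.63-fold), and by CG15214 at -2.06 (4.16-fold). EbpII, an ejaculatory bulb protein gene, stood at -1.94, RfC38, a subunit of the replication clamp loader, at -1.83 and the cohesin loader Mau2 at -1.68. CG15635 stood at -1.63, CG17784 at -1.59 and nht, a testis-specific TATA-binding protein associated factor, at -1.59. Polr1A, the large subunit of RNA polymerase I, had a value of -1.40, CG18549 of -1.31 and Ide, the insulin-degrading metalloproteinase, of -1.12 (2.18-fold). Each of these genes was measured by 1 probe, from 5 spots for nht to 10 for RfC38, CG15635 and Ide. For 6 of the 12 genes (Nepl15, RfC38, Mau2, CG15635, nht and Polr1A), the probe lay within 2 spots of another negative-side probe on the array.

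On the positive side, the lysosomal alpha-mannosidase gene LManVI stood furthest from 0 at 2.18 (4.52-fold), followed by Coq5, a methyltransferase of ubiquinone synthesis, at 1.79 (3.45-fold) and CG12057 at 1.58. The Tweedle cuticle protein genes TwdlD and TwdlK stood at 1.53 and 1.45. Amy-p, which encodes a digestive amylase, stood at 1.41 at both of its probes. Gnmt, a glycine methyltransferase that consumes S-adenosylmethionine, had a value of 1.35 and Mtk, the antimicrobial peptide metchnikowin, of 1.33. Arr2, the arrestin that ends rhodopsin signalling, stood at 1.28, CG15534 at 1.27 and CG4734 at 1.23 (2.34-fold). TwdlM stood at 1.38, but its 3 probes ranged from 0.13 to 1.92, wider than the SD between probes. LManVI, Coq5 and Amy-p had probes within 2 spots of another positive-side probe.

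**Figure D1:**
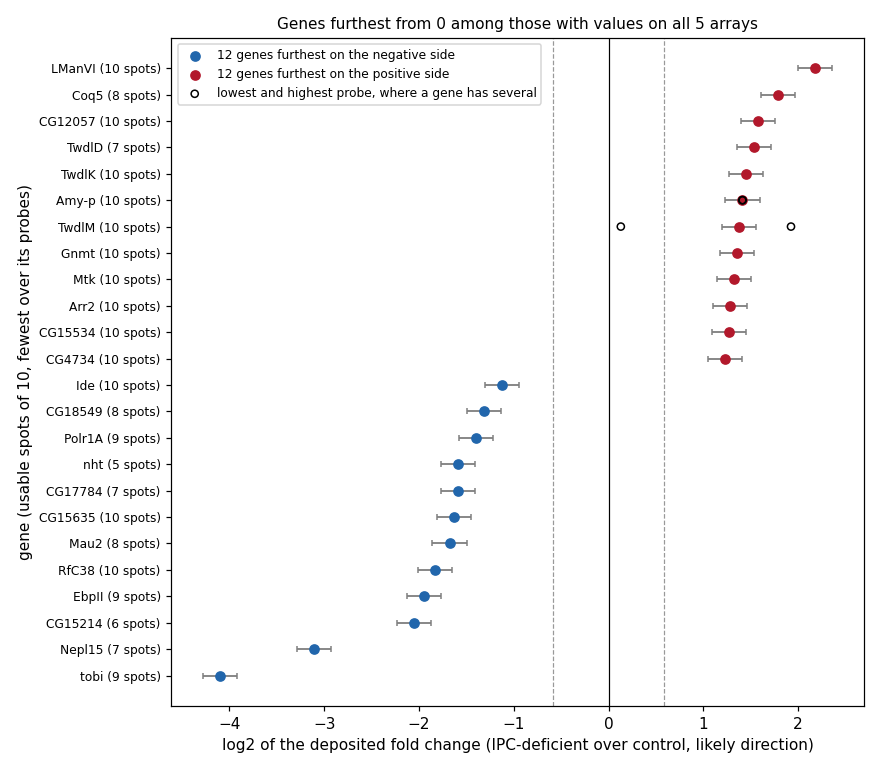
Log2 of the deposited fold change (x axis) of the 12 genes furthest on each side among genes with values on all 5 arrays (y axis), with bars of 1 SD between probes of a gene (0.18), open circles at the lowest and highest probe of genes with several probes, and dashed lines at 1.5-fold. The values run from -4.10 for tobi to 2.18 for LManVI, and the 3 probes of TwdlM span 0.13 to 1.92.

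At 1.5-fold or more, 227 of 10124 genes lay on the positive side and 315 on the negative side, so positive genes made up 41.9% of them. Restricted to the 6564 genes with every measured probe on all 5 arrays, 128 genes were positive and 48 negative, and the positive share was 72.7%. Probes with 1 usable spot lay beyond 1.5-fold on the negative side in 33.6% of cases and on the positive side in 13.0%, against 0.395% and 2.15% for probes with all 10 spots. Where a probe with at most 4 spots could be set against a probe of the same gene on all arrays, the absolute difference had a median of 0.42 and exceeded 1 in 28.0% of 329 probes. Among 1437 probes on all arrays, each set against the other such probes of its gene, the median was 0.11 and 0.626% exceeded 1.

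**Figure D2:**
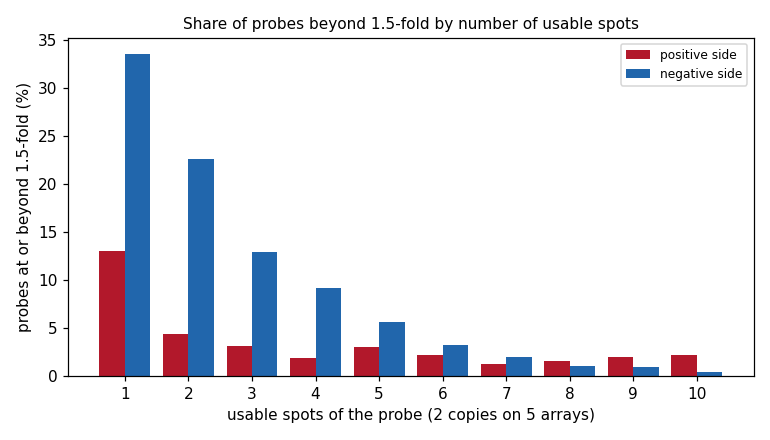
Percentage of named probes at or beyond 1.5-fold (y axis, positive side red, negative side blue) by the number of usable spots of the probe out of 10 (x axis). The negative-side percentage is 33.6% at 1 spot and 0.395% at 10 spots, while the positive-side percentage is 13.0% and 2.15%.

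Genes of carbohydrate and protein digestion stood mostly on the positive side. Of 12 alpha-glucosidase and amylase genes, 5 lay beyond 1.5-fold on the positive side and only tobi on the negative side. Of the 12, 8 were above 0 and 4 below. The median was 0.31, with a bootstrap interval of -0.16 to 0.68 that includes 0. Besides Amy-p, the maltase genes Mal-A3 and Mal-A1 stood at 0.95 and 0.73. Of 27 genes listed as gut serine proteases, 25 were above 0, with a median of 0.44. Of the 27, 7 lay beyond 1.5-fold on the positive side and 2 on the negative side. The list includes SPE at 0.15, a protease of immune signalling and not a gut enzyme. The trypsin gene lambdaTry stood at 0.84 and Jon25Biii at 0.79, whereas Ser12 stood at -0.82 and Jon99Ciii at -1.35 from 4 spots. No one of 10000 random lists of the same size had as high a median as either list. The 4 lysozyme genes had a median of 0.20, with LysX at 0.39, LysP at 0.24, LysE at 0.17 and LysS at -0.12. Their median lay above the central 95% of random lists, but not when the random lists were matched on usable spots. Markers of the midgut, 6 of 11 of which are themselves digestive enzymes or lysozymes, stood on the same side at a median of 0.33, 4 of them beyond 1.5-fold, with Peritrophin-A, a protein of the gut lining matrix, at 0.89 from 3 spots and Jon25Bi at 0.66. The 5 markers that are neither had a median of 0.04. Related genes in these families can cross-hybridise on spotted probes, so the values of single members are uncertain.

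Immune genes were divided. All 9 measured antimicrobial peptide genes were above 0, with a median of 0.39 that lay above the central 95% of random lists, and 2 were beyond 1.5-fold. These were Mtk and AttB, whose value of 1.57 averaged a probe at 0.25 and a probe with 1 spot at 2.89. Drsl5 stood at 0.45 and DptB at 0.39. The 16 other immune-induced genes had a median of 0.01 with 1 gene beyond 1.5-fold on each side, BomS4 at 0.72 and PGRP-SC1b at -0.89 from a probe with 1 spot at -1.82 and another at 0.03. PGRP-SC2 stood at -0.40. Hemocyte markers had a median of 0.11, inside the range of random lists, with the prophenoloxidase genes PPO1 and PPO2 at 0.72 and 0.54, the collagen gene vkg at 0.53 and Hml at -0.56 from 2 spots. Over the 5 hemocyte markers measured on all arrays the median was 0.53, above that range.

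Ovary genes stood on both sides. All 8 vitelline membrane and eggshell genes were below 0, with a median of -0.23 below the central 95% of random lists, Vm32E at -0.54, dec at -0.41, Femcoat at -0.37 and Vm34Ca at -0.35. The 7 chorion protein genes, whose products form the outer eggshell, had a median of 0.22 above that range, with Cp18 at 0.67, Cp19 at 0.29, Cp16 at 0.24 and Cp15 at 0.22. The yolk protein genes Yp1, Yp2 and Yp3 stood at -0.35, -0.18 and -0.03, and their median of -0.18 lay inside the range of random lists, as did the median of -0.07 over 13 female germ line genes. In that last list piwi stood at -0.27, bam at -0.24, spn-E at -0.23 and pum at -0.17. Apart from Cp18, no gene of these lists reached 1.5-fold. Send1, the measured spermatheca marker, stood at -0.27.

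Many genes of the respiratory chain and ATP synthase and of the cytosolic ribosomal protein list stood slightly above 0. Both lists were drawn mainly by name pattern and include paralogs such as ND-51L1 and RpS5b. Of 55 genes of the respiratory chain and ATP synthase, 46 were above 0 with a median of 0.09 and none beyond 1.5-fold, with ND-51 at 0.42, COX4 at 0.39, COX5A at 0.34 and ND-B8 at 0.43 from 2 spots. Of 30 cytosolic ribosomal protein genes, 27 were above 0 with a median of 0.19, and RpS5b stood at 0.54, RpLP1 at 0.46 and RpS21 at 0.38, while RpL39 stood at -2.41 from 3 spots. Both medians lay above the central 95% of random lists. Muscle markers had a median of 0.27 over 14 genes, 10 above 0 and 4 below, with a bootstrap interval of -0.02 to 0.40 that includes 0. Among them, fln (flightin, a thick filament protein of flight muscle) stood at 1.17 and the myosin light chains Mlc1 and Mlc2 at 0.54 and 0.47. Act88F stood at -0.58 from a probe with 4 spots at -2.76 and another at 1.60. All 7 photoreceptor markers were above 0 with a median of 0.35, led by Arr2 with Arr1 at 0.70, chp at 0.38 and trp at 0.35. Neuron markers had a median of 0.08, inside the random range, with nSyb at 0.48, nrv3 at 0.45, VAChT at 0.22 and brp at 0.13. Over the 6 neuron markers measured on all 5 arrays the median was 0.17, above that range.

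Transcripts known from male tissues stood on the negative side, although the labels give all flies as female. Of 9 accessory gland genes, 8 were below 0 and 3 beyond 1.5-fold with a median of -0.42, Acp95EF at -1.32 from 4 spots, Acp36DE at -0.90 and Acp62F at -0.87 from 3 spots each, and the sex peptide gene SP at -0.47. With at least 5 usable spots, 4 of these genes were left, with a median of -0.40 and 0 beyond 1.5-fold. Of 16 genes listed as testis markers, 13 were below 0 and 2 beyond 1.5-fold with a median of -0.13, Mst57Db at -3.20 from 4 spots, Mst98Cb at -0.59, Mst57Da at -0.35 and Mst87F at -0.27. Both medians lay below the central 95% of random lists, but the testis list did so only with its 3 Mst57D genes, which are known as accessory gland transcripts. Without them the other 13 testis markers had a median of -0.08, inside that range, and the accessory gland list with them had a median of -0.40 over 12 genes. Over the 8 testis markers measured on all 5 arrays, Mst57Da among them, the median was -0.04, also inside, while the 3 such accessory gland genes had a median of -0.38.

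The lists of lipid, carbohydrate and amino acid metabolism had medians inside the range of random lists. The 13 genes of lipid storage and lipolysis had a median of 0.08, with mdy at 0.41, mag at 0.31, Mtp at -0.24 and Lip1 at 0.20. Fatty acid synthesis had a median of -0.05 over 11 genes, with ACC at -0.55 from probes at -1.002 and -0.10, Lpin at -0.42, FASN1 at 0.31 and FASN3 at 0.23. Glycolysis stood at -0.06 over 9 genes, with Pgk at -0.21, Eno at -0.19, Gpdh1 at -0.14 and Hex-C at 0.20. Glycogen and trehalose metabolism stood at -0.03 over 8 genes, with Treh at 0.43, Tps1 at 0.30, Tret1-1 at 0.19 and UGP at -0.19. Gluconeogenesis and amino acid breakdown had a median of 0.02 over 9 genes, with the transaminase gene Got1 at -0.59 beyond 1.5-fold, Faa at 0.44, ry at -0.22 and Got2 at -0.18. Over the 7 of these genes measured on all 5 arrays the median was -0.17, below the random range. The 8 genes listed as fat body markers had a median of -0.06, and only the desaturase gene Fad2, at 1.02, was beyond 1.5-fold. The 3 larval serum protein genes had a median of -0.08 (Fbp1 at 0.56 and Fbp2 at -0.55 from 3 spots each, and Lsp2 at -0.08).

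Detoxification genes stood on both sides. The 32 glutathione S-transferase genes had a median of 0.07 above the central 95% of random lists, with 1 gene beyond 1.5-fold on each side, GstO3 at 0.59 and GstE7 at -2.31 from 2 spots, and GstE10 at 0.53 and GstE11 at 0.47. Of 79 cytochrome P450 genes, 4 were beyond 1.5-fold on the positive side and 3 on the negative side, and their median of 0.03 lay inside the random range. Cyp9b1 and Cyp4g1 stood at 0.82 each, Cyp301a1 at -1.001 and Cyp317a1 at -0.64, the last 2 from 3 spots. Over the 45 P450 genes measured on all 5 arrays the median was 0.08, above that range, and 4 were positive and 0 negative. The 32 UDP-glycosyltransferase genes had a median of 0.01 and 1 gene beyond 1.5-fold, Ugt35A1 at -0.70, with Ugt303B3 at 0.58, Ugt49B2 at -0.55 and Ugt35B1 at 0.41, and the 10 antioxidant genes had a median of 0.02, with Cat at 0.32, Prx6c at -0.31, Trx2 at -0.15 and Sod3 at 0.15.

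Odorant-binding protein genes stood on the positive side, with a median of 0.10 over 31 genes above the central 95% of random lists. Of these, 5 were beyond 1.5-fold on the positive side, among them Obp56d at 1.01, Obp56a at 0.97 and Obp19d at 0.67, and Obp69a stood at -0.69 from 1 spot. The 19 neuropeptide genes had a median of 0.09, above the random range, but not when random lists were matched on usable spots. Nplp3 stood at 0.44, Akh, the adipokinetic hormone gene, at 0.39 and Ms at 0.24, and Lk stood at 3.57 from a probe with 10 spots at 0.18 and a probe with 4 spots at 6.96. With at least 5 usable spots, 0 neuropeptide genes were beyond 1.5-fold. The 63 cuticle protein genes had a median of 0.03 with 1 positive and 2 negative at 1.5-fold, Cpr67Fa1 at 0.63, Cpr62Bc at -1.89 from 1 spot and Cpr65Eb at -1.80 from 3 spots, and Cpr67Fa2 stood at 0.55.

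The remaining lists lay inside the range of random lists. Heat shock protein genes had a median of 0.01 over 8 genes, 1 positive and 2 negative at 1.5-fold, but 0 with at least 5 usable spots. Hsp27 stood at -2.06 from a probe with 3 spots at -3.78 and another at -0.34, Hsp26 at -0.72 from a probe with 3 spots at -1.73 and another at 0.29, Hsc70-3 at 0.59 from 4 spots and Hsc70-4 at -0.38. Autophagy genes had a median of -0.04 over 16 genes and 1 beyond 1.5-fold, Atg18b at -0.62 from probes at -1.59 and 0.35, with Atg4b at -0.36, Atg2 at -0.31 and Atg9 at 0.20. Circadian clock genes had a median of 0.10 over 8 genes, with Pdp1 at 0.38, per at -0.12, cry at 0.12 and cyc at 0.11. Iron handling genes had a median of -0.02 over 6 genes, with Fer2LCH at 0.24, Fer1HCH at 0.22, Tsf1 at -0.13 and Mvl at -0.11. The measured cell death activators skl, grim and Dronc stood at -0.18, 0.15 and -0.10.

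**Figure D3:**
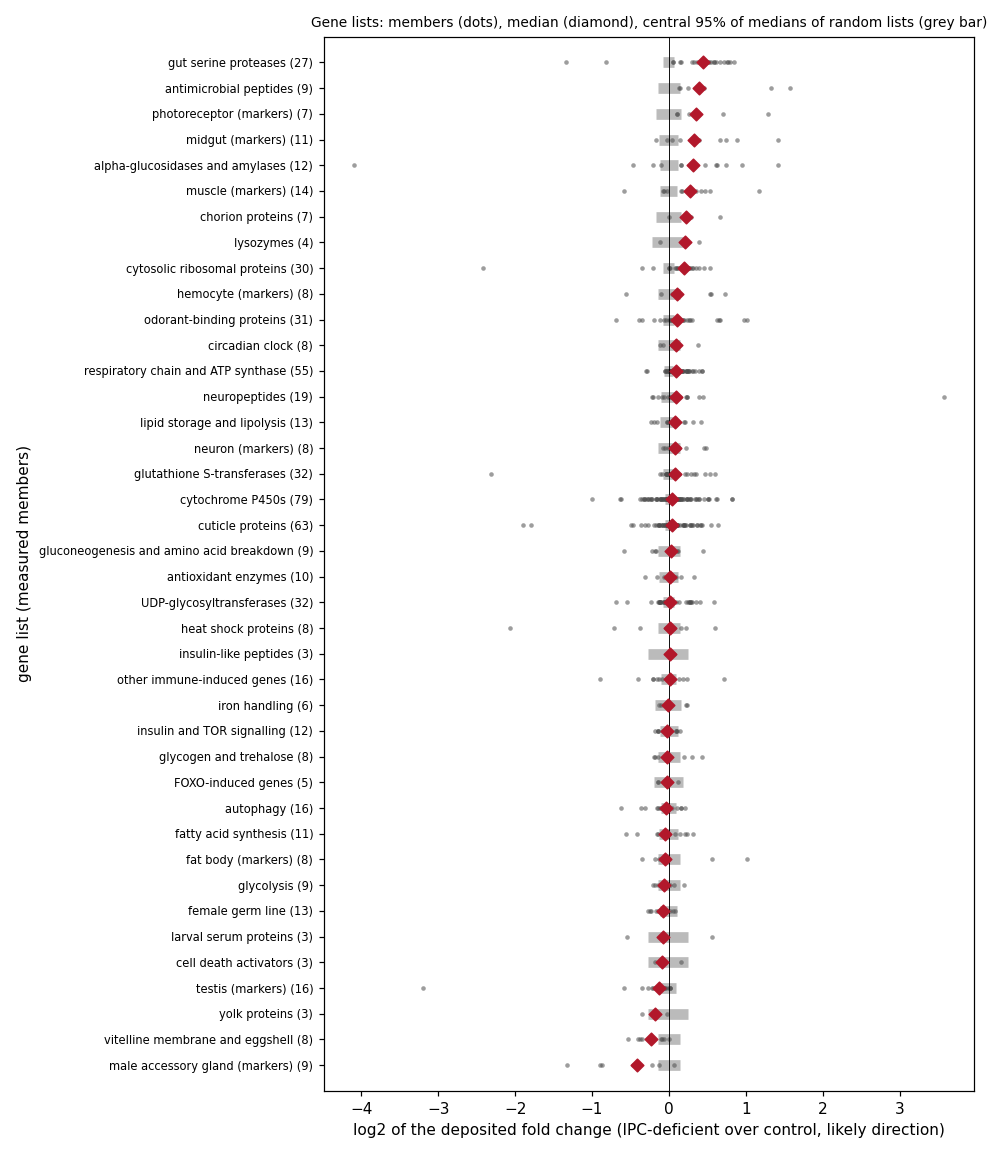
Gene lists with at least 3 measured members (y axis, number of members in brackets) against the log2 of the deposited fold change (x axis), with dots for members, a diamond for the list median and a grey bar for the central 95% of medians of 10000 random lists of the same size. Of the 40 lists, 13 have a median above the bar, led by gut serine proteases at 0.44, and 3 below it, led by male accessory gland at -0.42.

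Of the 40 lists with at least 3 measured genes, 13 had medians above the central 95% of random lists and 3 below. The testis list was among the 3. About 1 on each side would be expected for lists of genes drawn independently. Members of a list are often related and some lists share genes, so more than this may arise by chance. These percentiles describe how the lists stood among the genes of these RNA samples and are not tests across flies. The lines differed in their transgenes and possibly in genetic background, which cannot be told apart from the loss of the cells.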

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

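The tests of the patterns in this part were chosen after the result was seen, except the comparison of dye orientations among weak spots, which was written before its result.

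Probes without a gene name, which entered no comparison, held values far from 0. A single value of -610.52-fold was shared by 33 such probes in 70 filled spots. Among 1368 unnamed probes with a value of their own on all 5 arrays, the lowest stood at -170.042-fold and the highest at 100.588-fold, each in 10 spots. Of the 1368, 20 lay beyond 1.5-fold on the positive side and 22 on the negative side. Of 7944 named probes on all 5 arrays, 152 lay beyond it on the positive side and 59 on the negative side.

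Probes with few usable spots lay on the negative side. Of 351 probes with at most 4 spots beyond 1.5-fold, 80.3% were negative (95% interval 75.9 to 84.2). This share is the pattern itself, counted after it was seen. It argues only against noise without a direction that is independent between probes. Noise shared by probes on 1 array stays open, since 1815 probes with at most 4 spots had array 3 among them and 88 did not. Lower transcript levels in the deficient flies are argued against only for the 105 genes with a negative weak probe that also had a probe on all arrays, with a median of 0.014 (-0.0041 to 0.035) there, and stay open for 171 other genes, of which 7 had another probe with at least 5 spots. A dye effect may remain. Probes seen only with IPC-deficient RNA in Cy5 had a median of 0.069 (-0.15 to 0.57, 38 probes). Those seen only with it in Cy3 had a median of -0.14 (-0.19 to -0.09, 463 probes). The prediction for a dye effect was medians of opposite sign, which these were, but the first interval includes 0. The negative share of those beyond 1.5-fold was 38.1% against 88.5% (Fisher's exact test, two-sided p = 1.59e-06), and it was 83.4% with array 3 among the filled spots against 55.3% without it (p = 0.000159), with probes and not flies as units, so dye and array 3 cannot be told apart.

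Digestive enzyme genes lay on the positive side, with a median of 0.44 (0.33 to 0.58) over 39 alpha-glucosidase, amylase and serine protease genes. SPE, counted among the 39, is not a gut enzyme. A shift of the centre of the authors' normalization would move all genes alike. It would leave the lists' standing among genes unchanged by construction. That 0 of 10000 random lists had a higher median than either list is therefore no test of such a shift. Whether these genes would lie above 0 with another centre stays open. The deposited values are centred, and this fixes the median of all genes near its -0.0077. More gut tissue in the RNA may contribute. The 17 midgut genes that are not digestive enzymes had a median of 0.14 (0.03 to 0.27), above 0. Its interval includes the bound of 0.22, the digestive median divided by 2. The 5 of the 17 that were fixed as markers before the data were examined had a median of 0.04. Cross-hybridisation stays open, since only 4 of the 39 genes were the sole measured gene of their name stem, and the minimum of 5 such genes was set after an earlier minimum of 3 had let these 4 count in its favour. Loss of the insulin-producing cells and a difference between the lines also stay open, as untested.

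Transcripts of male tissues lay on the negative side, with 21 of 25 genes below 0 and a median of -0.22. With the Mst57D genes counted as accessory gland, that tissue had a median of -0.40 over 12 genes and the testis of -0.08 over 13, the second inside the range of random lists. A skew tied only to the number of usable spots is argued against, since 0.01% of random lists matched on that number had a lower median. The random lists were not matched on dye or array, so a skew tied to those stays open. Of the 25 genes, 11 had at most 4 spots. Male RNA in the control sample may be present, as the 14 genes with at least 5 spots had a median of -0.15 (-0.38 to -0.04, 11 below 0), but this interval includes the bound of -0.1 that was set. The loss of the insulin-producing cells and a difference between the lines stay open, as untested.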

How the results depend on the processing

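The alternatives restricted to probes with at least 5 spots, to calls without neighbours on the array, to 2-fold on all 5 arrays, and to lists over genes on all arrays or matched on usable spots, and the Mst57D genes counted as accessory gland, were chosen after seeing the data. The count of genes on each side, 227 positive and 315 negative, depended on how well probes were measured and on the threshold. At 2-fold there were 72 positive and 147 negative genes, and with values on all 5 arrays 128 and 48. With at least 5 usable spots there were 179 and 110 genes, with all 5 arrays and no other call beside them 97 and 35, and with all 5 arrays at 2-fold 26 and 15. Fewer genes passed the stricter filters by construction, but the cause of the larger loss on the negative side was not tested there. Centring (223 and 314), the mean over probes (230 and 323), the probe furthest from 0 (259 and 405) and genes with a single probe (200 and 262) stayed within 1.5 times of the counts. Turning the sign only swaps the counts by construction (315 and 227), so it is no check of their stability. The 13 lists above and 3 below the random range were 12 and 3 with random lists from genes on all 5 arrays, 14 and 3 over genes on all 5 arrays, 14 and 2 with at least 5 spots, 11 and 3 with matched random lists, and 13 and 3 with centring or the mean over probes. At 2-fold, 8 positive and 10 negative genes of any list were left of 35 and 22. Of 108 alternative values of named genes, 105 stayed within 1 SD between probes, and 0 of those called changed sign. The 3 others were TwdlM at 1.14 as the mean and at 0.13 and 1.92 at its lowest and highest probe. For genes with 1 probe the probe rules give the same value by construction, and centring shifts values little. Only Amy-p and TwdlM, with 2 and 3 probes, could move under the probe rules, so this count says little about the other genes. Of 202 alternative list medians, 201 stayed inside the bootstrap interval of the list, which is wide for small lists. The testis markers on all 5 arrays (-0.04) did not. Random lists from genes on all 5 arrays leave list medians unchanged by construction, and centring barely moves them, so this count overstates their stability. Against random lists, 7 lists changed their standing under an alternative. Lysozymes, neuropeptides and testis markers came inside the range. Over genes on all 5 arrays, P450s (0.08), hemocyte (0.53) and neuron markers (0.17) came above it. Gluconeogenesis and amino acid breakdown (-0.17) came below it there. No paired analysis was possible because the table holds 1 value for all arrays. For the same reason the limma fits, quantile normalization, the dye term, the left-out arrays, the missing-value filter and the sign flips were not run, and natural log or linear scales were not run because the values decide the scale. Signal over background is not known for these values, so usable spots stand in for it.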

Other observations

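The families, genome neighbours and array positions in this part were picked after their values were seen, and so were the shuffles.

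All 6 measured lysosomal alpha-mannosidase genes were above 0, with a median of 0.91, and 4 were beyond 1.5-fold: LManVI at 2.18, LManV at 1.08, LManIII at 1.01 and LManI at 0.81, while LManIV stood at 0.17 and LManII at 0.06. The Tweedle family of cuticle proteins had a median of 0.14 over 18 genes, with TwdlF at 0.98 beside TwdlD, TwdlK and TwdlM as the 4 genes beyond 1.5-fold and TwdlS at -0.48. Ejaculatory bulb protein genes were divided, with EbpII at -1.94, Ebp at -1.08 and EbpIII at 0.59.

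Positive-side genes with values on all 5 arrays were often next to each other in the genome order of a reduced set of genes. This order held 6392 of the 10124 genes with a value. Genes outside it were skipped, so genes adjacent in it need not be neighbours in the genome. Among 127 positive-side genes in this order, 18 adjacent pairs were found. The central 95% of shuffles gave 0 to 6 and the highest of 10000 gave 11. The 13 runs held 31 genes, and the 5 runs of 3 genes were LManIII, LManV and LManVI, then CG8997, CG7916 and CG7953, then Mal-A1, Mal-A2 and Mal-A3, then lambdaTry, kappaTry and zetaTry, then Obp56a, Obp56d and Obp56e. Such clusters often hold related genes whose probes can cross-hybridise, and no explanation was tested.

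Negative-side probes lay beside each other on the array more often than shuffled positions did. Of 59 such probes with values on all 5 arrays, 17 had another within 2 spots, where shuffles gave 0 to 11 and 2 of 10000 reached 17. For 152 positive-side probes the number was 33, inside the range of 18 to 43 from shuffles.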
